A study of Homo sapiens with 3 samples.

How the data were processed

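The series holds 3 samples of the H-Ras-transformed breast epithelial cell line MCF10A MII. They are a SMAD2/3 ChIP-seq library at 1.5 h and one at 16 h after 5 ng/ml TGFβ3, and an input DNA library of untreated cells. Grouping followed the treatment label. Each time point had 1 library, so there was no replicate and no spread between samples.

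The authors deposited a peak list for each ChIP library, as BED intervals with a MACS score per peak and no header. The submitters' processing notes name Bowtie 1.1.0, Picard and MACS 1.4.2, and the genome build hg19. The settings, the handling of duplicate reads and the use of the input library as control are not given in the sources used here. The lowest deposited score was 50.02 at 1.5 h and 50 at 16 h, which is what minus 10 times log10(p) gives at a p of 1e-05. The definition of the score is otherwise not given in the sources used here, so scores served to rank and class peaks within a list. Scores and score classes of both lists were also set side by side, and scores of overlapping peaks were correlated, but no ratio or difference of scores between the libraries was computed. Peaks were listed per library. No labels mention pooled samples. Because a fixed p threshold yields more peaks from a deeper library, and depth is unknown from the lists, peak numbers and scores at the 2 times reflect sequencing as well as binding.

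Starts were converted to 1-based positions. Peaks overlapping a peak of the other list by at least 1 bp were called shared, and all others 1.5 h only or 16 h only. Shares carry 95% exact Clopper-Pearson intervals, which cover counting error only. Chance overlap was estimated from 1000 shifts, in each of which all peaks of a chromosome moved by one random distance around the span of the listed peaks. This keeps the spacing of peaks but not any preference for open or mappable sequence. Median score and width of shared and time-only peaks were compared with 100000 permutations within a list (two-sided). Score pairs were overlapping peaks that were each other's best match. Shares of peaks were compared between lists with Fisher's exact test (two-sided) with Benjamini-Hochberg adjustment. Runs of peaks joined neighbours at most 10 kb apart over both lists. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The overlap and permutation code was tested on 20 simulated pairs of lists of the real sizes (2206 and 3280 peaks). With 25% of the 1.5 h peaks planted in the 16 h list as exact copies, all planted overlaps (100%) were found, which was certain for copies. The planted overlap was called in 20 of 20 sets, and 0 of 20 independent sets were called. Offsets between overlapping peaks and clusters of peaks were not simulated. A score difference of 20 was called in 20 of 20 sets and no difference in 1 of 20.

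The design fixed before the data were examined also held the position of peaks relative to genes, a search for 23 sequence motifs and a test of 17 gene lists near peaks. These need the hg19 sequence and annotation, which were not used here. The gene table at hand describes another build, GRCh38, and coordinates were not converted between builds, so no peak was assigned to a gene and no gene is named. The rule for named items was to name the genes nearest to the 10 peaks of highest score in each of 3 classes (shared by 16 h score, 1.5 h only, 16 h only), and the 5 genes with most peaks at each time. It was applied to the peaks themselves and to runs of peaks in place of genes. The alternatives fixed with it were a score of at least 100, equal list lengths, chromosomes 1 to 22 and X only, a reciprocal overlap of 50% and a distance of up to 500 bp. After the data were seen, 3 alternatives were added, namely a score of at least 60, merging of peaks under 500 bp apart, and leaving out the first 50 Mb of chromosome 5. The runs, the 10 highest 1.5 h peaks, the score classes and the comparisons by chromosome were also chosen after the lists were seen.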

Results

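Binding of SMAD2/3, the receptor-regulated transcription factors through which TGFβ signals, was profiled by ChIP-seq in MCF10A MII cells. MCF10A MII is a human breast epithelial cell line transformed with H-Ras. Chromatin was immunoprecipitated with an antibody that recognises both SMAD2 and SMAD3, 1.5 h and 16 h after addition of 5 ng/ml TGFβ3, with 1 library at each time. An input DNA library from untreated cells was the only other sample and was not analysed here. The comparison implied by this design is between early and late SMAD2/3 binding during TGFβ stimulation. Each time point has a list of peak positions on hg19, each peak with the authors' MACS score. With 1 library per time, no value has a replicate error, and read numbers per peak and sequencing depth are unknown from the lists. The p-values below compare peaks between or within these 2 lists, not the 2 conditions.

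More SMAD2/3 peaks were listed at 16 h than at 1.5 h, and the surplus lay among the peaks of lowest score. The 1.5 h list held 2206 peaks covering 394 kb and the 16 h list held 3280 peaks covering 482 kb, a ratio of 1.49. Among peaks scoring 50 to 60, just above the lowest score listed, there were 785 peaks at 1.5 h and 1999 at 16 h, a ratio of 2.55. In each higher score class the 16 h list was the shorter one. It held 692 peaks against 736 at scores of 60 to 80, 212 against 241 at 80 to 100, 260 against 314 at 100 to 200, and 117 against 130 at 200 or more. Peaks scoring 100 or more, called high-score peaks from here on, numbered 444 at 1.5 h and 377 at 16 h, which made up 20.1% and 11.5% of the respective lists. The median score was 64.9 (quartiles 57.3 and 90.3) at 1.5 h and 56.2 (quartiles 52.5 and 68.8) at 16 h. The median peak width was 130 bp at 1.5 h and 108 bp at 16 h. A score depends on sequencing depth as well as on enrichment, so numbers above a given score need not mean the same at both times. With peaks under a score of 60 left out, the 16 h list had 140 fewer peaks than the 1.5 h list, 1281 against 1421, which turned the direction of the difference.

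**Figure D1:**
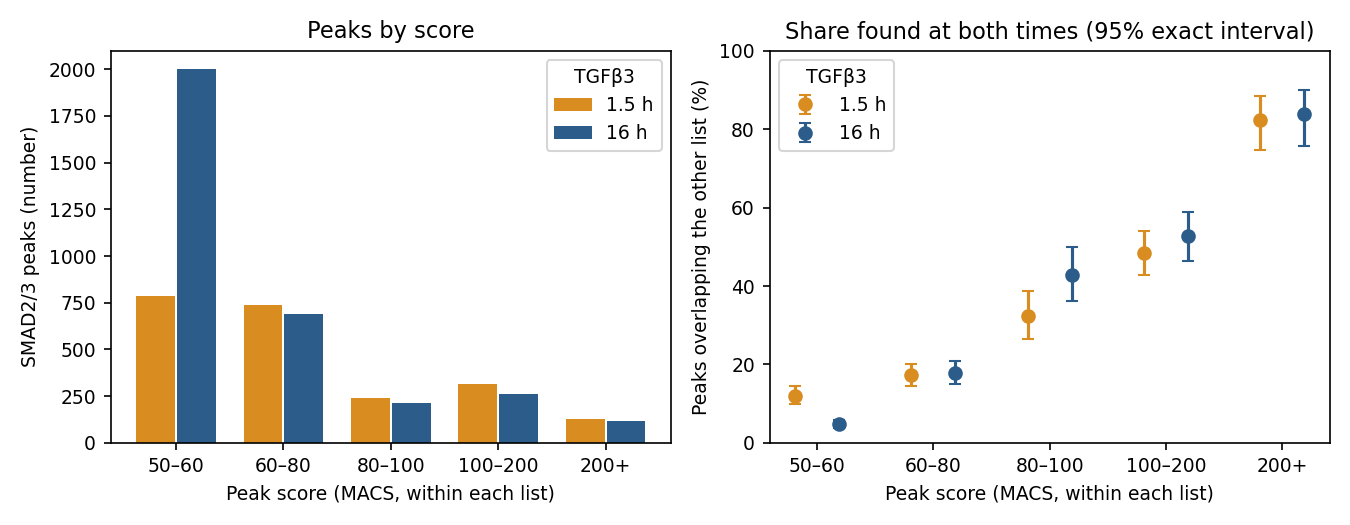
Left, number of SMAD2/3 peaks by score class (bars) at 1.5 h and 16 h after TGFβ3; right, percent of the peaks of each class that overlap a peak of the other list (points, with 95% exact binomial intervals). The 16 h list exceeds the 1.5 h list only in the class from 50 to 60, with 1999 against 785 peaks, and the share found at both times rises with score to above 80% in both lists.

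A minority of all sites was listed at both times, but most of the sites with the highest scores were. Of the 1.5 h peaks, 558 (25.3%, 95% exact binomial interval 23.5 to 27.2%) overlapped a 16 h peak by at least 1 bp. Of the 16 h peaks, 544 (16.6%, interval 15.3 to 17.9%) overlapped a 1.5 h peak. When all peaks of each chromosome were shifted together by a random distance, an average of 0.892 and at most 6 of the 1.5 h peaks were overlapped in 1000 shifts (one-sided permutation p = 0.001, the smallest these shifts can give). The shared share rose with score within each list. At 1.5 h it was 12.0% (9.79 to 14.5%) for scores of 50 to 60, 48.4% (42.8 to 54.1%) for 100 to 200 and 82.3% (74.6 to 88.4%) for 200 or more. At 16 h the corresponding shares were 4.75% (3.86 to 5.78%), 52.7% (46.4 to 58.9%) and 83.8% (75.8 to 89.9%). These intervals cover counting error only. Requiring that overlap cover at least 50% of both peaks lowered the shared shares to 12.8% and 8.60%.

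Shared sites had higher scores and were wider than sites listed at a single time. At 1.5 h the median score was 92.7 for 558 shared peaks and 61.9 for 1648 peaks found only at 1.5 h, and the median widths were 188 and 118 bp. At 16 h the median score was 91.3 for 544 shared peaks and 54.4 for 2736 peaks found only at 16 h, and the median widths were 210 and 105 bp. All of these differences were larger than in any of 100000 permutations of the peaks within a list (two-sided permutation p = 1e-05, the smallest these can give). In 494 one-to-one pairs of overlapping peaks, the midpoints lay a median of 58.8 bp apart. Scores of the pairs were correlated across peaks, with Spearman's rho 0.38 and Pearson's r 0.58 (permutation p = 1e-05 for each, 2 coefficients computed, so the adjusted values are the same). Without the 2 pairs whose 1.5 h scores lay farthest from the median, r was 0.60. Where the overlap had to cover at least 50% of both peaks, 282 pairs remained and rho was 0.64. That rule keeps pairs of similar width, and median width rose with score class in both lists. The higher rho may therefore partly follow from the rule. Peaks are not independent replicates.

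The 10 highest-scoring shared sites at 16 h lay on chromosomes 3, 4, 5, 9, 17, 18 and 20. Chromosome 9 held the first, at 136739050 to 136739902, with a score of 1650 at 16 h and 1250 at 1.5 h. It also held the second, at 72735636 to 72736261, with scores of 1116 and 670. Chromosome 3 carried a site at 170075049 to 170075629, which scored 900 at 16 h and 875 at 1.5 h, and another at 72387562 to 72388628, which scored 654 and 989. The highest 1.5 h peak of all, on chromosome 20 at 56592228 to 56593581, scored 1839 at 1.5 h and 722 at 16 h. The remaining shared sites of this group were on chromosome 4 at 166501279 to 166502012, chromosome 18 at 73336703 to 73337245, chromosome 17 at 76588399 to 76588907, and chromosome 5 at 136806123 to 136806786 and 17181039 to 17181874. Those on chromosome 5 scored 724 and 606 at 16 h and 361 and 313 at 1.5 h. Scores of different libraries were set side by side here and not tested.

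All 10 of the highest-scoring 1.5 h peaks were also listed at 16 h, with scores there between 131 and 1650. The second of them, on chromosome 8 at 128680119 to 128681625, scored 1363 at 1.5 h and 131 at 16 h. The seventh, on chromosome 2 at 228682790 to 228683859, scored 931 at 1.5 h and 149 at 16 h. The eighth, on chromosome 5 at 135342224 to 135343308, scored 924 and 184, and the tenth, on chromosome 14 at 75086127 to 75087037, scored 809 and 181. The chromosome 2 site at 238341110 to 238342153 scored 987 and 451, and the chromosome 5 site at 143569336 to 143570019 scored 942 and 414.

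Some high-score sites were listed at 1 time only. At 1.5 h, 185 of 444 high-score peaks (41.7%) had no overlapping 16 h peak, and 133 of these had none within 10 kb. The highest was on chromosome 5 at 78075345 to 78075994, with a score of 519 and the nearest 16 h peak 171 kb away. Chromosome 16 carried 4 of the 10 highest 1.5 h only sites. These were at 65692217 to 65692883 (score 513), 56640826 to 56641594 (score 504), 86857962 to 86858742 (score 483) and 72325234 to 72325771 (score 314), with the nearest 16 h peaks between 133 and 3218 kb away. Others were on chromosome 5 at 148345380 to 148346258 (score 459), chromosome 2 at 201809174 to 201809904 (score 413), chromosome 9 at 110803049 to 110803575 (score 394), chromosome 3 at 183088529 to 183089035 (score 317) and chromosome 1 at 17559865 to 17560590 (score 292).

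At 16 h, 142 of 377 high-score peaks (37.7%) had no overlapping 1.5 h peak, and 118 had none within 10 kb. The highest was on chromosome 7 at 144750810 to 144751382, with a score of 630 and the nearest 1.5 h peak 2707 kb away. It was followed by sites on chromosome 19 at 42440524 to 42441182 (score 326), chromosome 9 at 33193733 to 33194154 (score 322) and chromosome 3 at 196070014 to 196070413 (score 269). Of the other 6 in the first 10, the chromosome 1 site at 146643938 to 146644337 (score 244) and the chromosome 17 site at 7745931 to 7746373 (score 252) lay only 103 and 935 bp from a 1.5 h peak. The chromosome 17 site at 48261512 to 48261746 (score 244) lay 5.45 kb from one, and the chromosome 10 site at 5606059 to 5606475 (score 239) lay 12.2 kb from one. The last 2 were on chromosome 11 at 11334937 to 11335378 (score 243) and chromosome 3 at 5068183 to 5068539 (score 240). A site absent from a list may have been just below the authors' threshold there. Where an overlap of at least 50% of both peaks was required, the numbers of high-score peaks found at 1 time only rose to 283 at 1.5 h and 241 at 16 h.

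SMAD2/3 peaks also occurred in runs, defined as stretches in which successive peaks of either list lay at most 10 kb apart. There were 3989 runs, of which 536 held peaks of both times, 1101 of 1.5 h only and 2352 of 16 h only. Of the 576 runs with a high-score peak, 342 (59.4%) held peaks of both times, against 194 of the other 3413 runs (5.68%). The run with most 1.5 h peaks was on chromosome 20 at 56267857 to 56274147, with 10 peaks at 1.5 h and 3 at 16 h. Its highest scores were 500 at 1.5 h and 469 at 16 h, and all 3 of its 16 h peaks overlapped a 1.5 h peak. A run on chromosome 10 at 74079196 to 74095118 held 7 peaks at 1.5 h and 3 at 16 h, and one on chromosome 5 at 135341850 to 135356516 held 7 and 1. A run on chromosome 14 at 101438766 to 101460730 held 6 and 2, with no score above 77.4. On chromosome 17, a run at 38666445 to 38678934 held 7 peaks at 1.5 h, scoring up to 142, and none at 16 h.

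**Figure D2:**
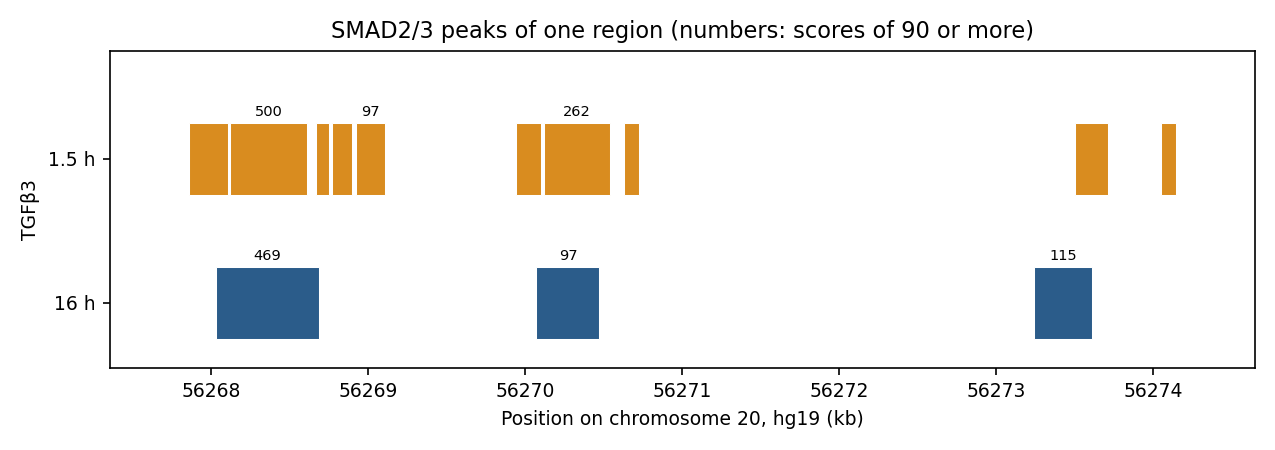
SMAD2/3 peaks (boxes, to scale) in the run on chromosome 20 from 56267857 to 56274147 (x axis, hg19 position in kb) at 1.5 h (top) and 16 h (bottom), with the scores of those at 90 or more. The 10 peaks at 1.5 h and the 3 at 16 h fall on the same stretch, and the highest of each, scoring 500 and 469, overlap.

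Among the runs richest in 16 h peaks, one on chromosome 17 at 48255744 to 48271372 held 11 peaks at 16 h and 1 at 1.5 h. Its highest score was 244 at 16 h and 50.6 at 1.5 h. A run on chromosome 1 at 183214779 to 183220354 held 7 peaks at 16 h, scoring up to 113, and none at 1.5 h. A run on chromosome 12 at 95508785 to 95510737 held 5 peaks, scoring up to 89.1, and none at 1.5 h. On chromosome 19, a run at 49541883 to 49554152 held 4 peaks at 1.5 h and 6 at 16 h. The run with most 16 h peaks was on chromosome 21 at 10700529 to 10724968, with 12 peaks at 16 h and 1 at 1.5 h. No region was filtered out before runs were formed, and the input library was not analysed. Whether a run marks clustered binding was therefore not tested. Runs with at least 3 peaks of 1 list and none of the other numbered 39 for 1.5 h and 12 for 16 h. Neighbouring peaks lay close together more often in the 1.5 h list, with 424 gaps under 500 bp against 228 at 16 h. The numbers of peaks in a run may therefore partly count pieces of one site. With such neighbours merged, 1782 and 3052 peaks remained.

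Peaks found at a single time were distributed differently over the chromosomes at the 2 times. Relative to the 1648 peaks found only at 1.5 h, the 2736 found only at 16 h had larger shares on chromosomes 4, 5 and X and smaller shares on chromosomes 1, 8, 16 and 22. Shares sum to a whole, so a smaller share need not be a smaller number: chromosome 1 held 156 such peaks at 1.5 h and 198 at 16 h, and chromosome 8 held 92 and 105. On chromosome X the shares were 1.58% (1.03 to 2.30%) at 1.5 h and 3.73% (3.05 to 4.51%) at 16 h. On chromosome 4 they were 3.40% (2.58 to 4.39%) and 6.40% (5.51 to 7.38%). On chromosome 5 they were 8.01% (6.74 to 9.43%) and 12.2% (10.97 to 13.5%). On chromosome 16 they were 3.52% (2.68 to 4.53%) and 1.90% (1.42 to 2.48%). These 7 of 24 chromosomes passed Fisher's exact test (two-sided, Benjamini-Hochberg adjusted over 24), with an adjusted p of 0.000161 for chromosomes 4 and 5 and 0.000206 for chromosome X. The test treats neighbouring peaks as independent, and this comparison was chosen after the lists were seen. With equal list lengths, 4 chromosomes passed, and chromosomes 1, 16 and 22 no longer did. That cut kept 16 h peaks tied at the cut score by chromosome name, with 1, 16 and 22 ahead of 4, 5, 8 and X. The number of peaks tied at the cut score was not computed. This loss may come from the tie rule, which was not tested. Chromosome 22 also no longer passed with a reciprocal overlap of 50%, within 500 bp or with merged neighbours. Chromosome 8 was lost with the reciprocal overlap, and chromosome 1 with merged neighbours. Without the first 50 Mb of chromosome 5, 3 passed, with chromosomes 4 and X larger and 16 smaller at 16 h. Among all high-score peaks, shared ones included, none of the 24 chromosomes passed (lowest unadjusted p = 0.0851, chromosome 8, Fisher's exact test), so 0 had an unadjusted p under 0.05. With peaks scoring under 60 left out of both lists, none passed among time-only peaks either, and 4 had an unadjusted p under 0.05 (Fisher's exact test). Fewer peaks remained for this test, and the odds ratios of 16 h against 1.5 h were 2.32 on chromosome X, 1.51 on chromosome 4 and 1.34 on chromosome 5 (Fisher's exact test, adjusted p = 0.167, 0.273 and 0.273), against 2.42, 1.94 and 1.59 in the full lists.

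**Figure D3:**
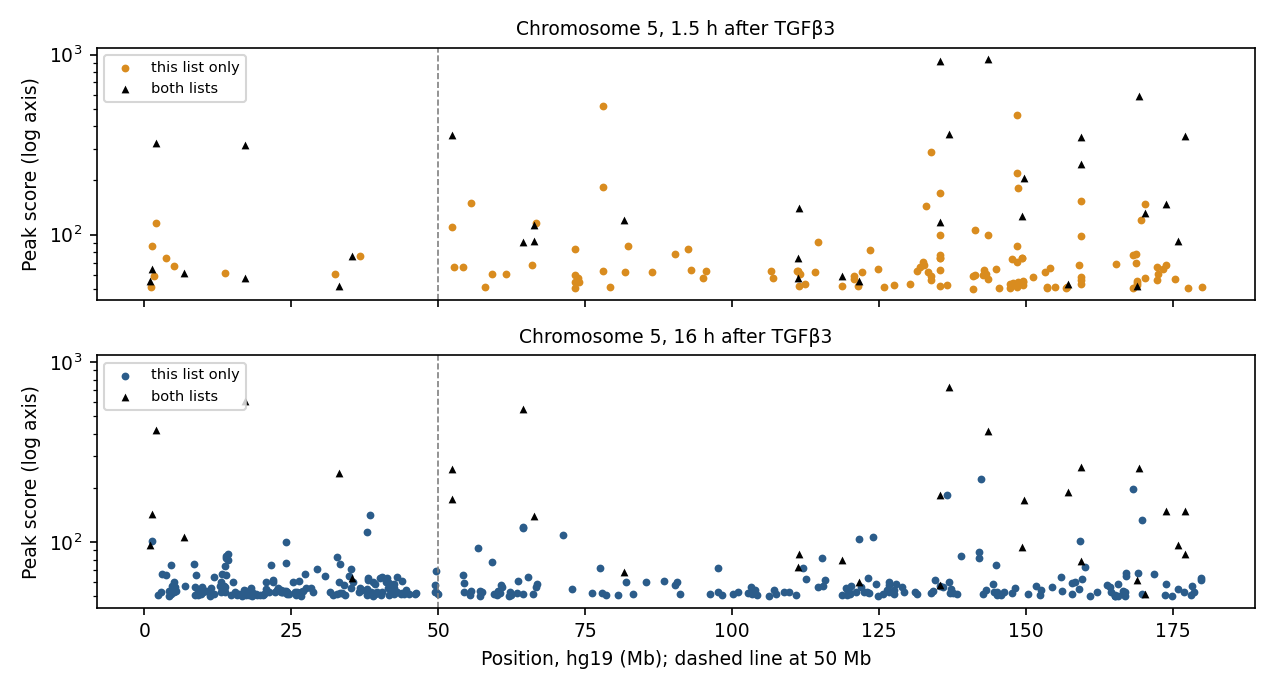
Score (y axis, log scale) against position on chromosome 5 (x axis, hg19 Mb) of each SMAD2/3 peak at 1.5 h (top) and 16 h (bottom); triangles are peaks that overlap a peak of the other list and circles are peaks of one list only. Left of the dashed line at 50 Mb lie 17 peaks at 1.5 h and 173 at 16 h, most of the latter with scores under 60.

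The excess on chromosome 5 lay in its first 50 Mb, a segment whose limit was drawn after the excess was seen, so that the p-values for it describe these lists and are too small as tests. This segment held 17 of the 2206 peaks at 1.5 h (0.771%, interval 0.450 to 1.23%) and 173 of the 3280 at 16 h (5.27%, interval 4.53 to 6.10%). The rest of the chromosome held 148 and 192 peaks. Of the 173 peaks, 124 scored under 60, 40 scored 60 to 100 and 9 scored 100 or more, against 5, 9 and 3 at 1.5 h. The odds ratio of 16 h against 1.5 h was 10.3 under a score of 60 (Benjamini-Hochberg adjusted p = 1.23e-12), 4.98 at 60 to 100 (adjusted p = 2e-06) and 3.60 at 100 or more (adjusted p = 0.0756), each by Fisher's exact test and adjusted over only 4 comparisons, these 3 and all scores together. Without this segment, the odds ratio for time-only peaks on chromosome 5 turned to 0.857 (adjusted p = 0.302, Fisher's exact test).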

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

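The 3 alternatives named in the methods as added were chosen after seeing the data. The excess of shared sites over shifted lists and the higher median score and width of shared peaks kept their direction and stayed past their threshold under all 8 alternatives, as did the correlation of paired scores (rho 0.32 to 0.64), though restricting the chromosomes changed no pair. With a score of at least 100, the lists held 444 and 377 peaks and the difference turned to -67. Here and with the cut at 60, overlap was called after the cut, so a peak whose only partner fell below it counted as time-only. Shared shares were then 35.1% at 1.5 h and 40.8% at 16 h. At 1 time only, 288 and 223 high-score peaks were found, against 185 and 142 in the full lists. Among these time-only peaks, 0 chromosomes differed by Fisher's exact test after adjustment (1 at an unadjusted p under 0.05). The odds ratios were 1.30, 1.13 and 1.95 on chromosomes 4, 5 and X, against 1.94, 1.59 and 2.42 in the full lists. With a score of at least 60, the lists held 1421 and 1281 peaks, the difference turned to -140, shared shares were 28.5% and 30.6%, and again 0 chromosomes differed (4 unadjusted), with odds ratios of 1.51, 1.34 and 2.32. Both reversals follow from removing the class in which the 16 h list is longer. With equal list lengths the difference is 0 by construction, the shared share at 16 h was 22.6%, and 4 chromosomes differed. Peaks tied at the cut score were kept there by chromosome name, which may have changed the chromosomes that differed. A reciprocal overlap of 50% gave shared shares of 12.8% and 8.60%, with 283 and 241 high-score peaks at 1 time only. A distance of up to 500 bp gave 35.1% and 20.2%. Merged neighbours gave 15.1% at 16 h. Without the first 50 Mb of chromosome 5, 3 chromosomes differed and the odds ratio of chromosome 5 turned to 0.857. Alternatives for gene positions, motifs and gene lists were not run, since no hg19 sequence or annotation was used. No paired analysis was possible because each time point has 1 library, and for the same reason no library could be left out. Depth is unknown for both libraries, so whether a site listed at 1 time only was unbound at the other time or missed there was not tested.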

Other observations

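All tests in this part concern patterns found in these lists. The tests of overlap under a score of 60, of the strength of peaks on chromosome 5 and of bins of 10 Mb were chosen after the result was seen.

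Chromosomes rich in high-score SMAD2/3 peaks were also rich in low-score peaks at 1.5 h, but this was not detected at 16 h. Across 23 chromosomes, peaks per Mb scoring under 60 and scoring 100 or more had Spearman's rho 0.76 and Pearson's r 0.79 at 1.5 h (permutation p = 4e-05 and 1e-05, adjusted over 4 coefficients 8e-05 and 4e-05), and r was 0.73 without the 2 chromosomes farthest from the median. At 16 h rho was 0.25 and r 0.32 (permutation p = 0.244 and 0.137, adjusted 0.244 and 0.183), and r was 0.29 without 2 chromosomes. The difference between the times was not tested.

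The surplus of low-score peaks at 16 h was compared with background calls. The 16 h peaks scoring under 60 overlapped 1.5 h peaks in 4.75% of cases, against at most 0.150% in 1000 shifted lists (permutation p = 0.001). Of the 1904 that did not overlap, 101 (5.30%) lay within 10 kb of a 1.5 h peak, against a maximum of 40 in shifted lists (permutation p = 0.001). For the 691 such peaks at 1.5 h, 111 (16.1%) lay within 10 kb of a 16 h peak, against a maximum of 31. Both tests argue against background placed without regard to the 1.5 h list as the source of all these peaks. The shifts keep no preference for open or mappable sequence, so background recurring at the same places in both libraries is not excluded. Peaks within 10 kb may also include pieces of shared sites. A mixture that may be mostly background stays open, as the rho of 0.25 across chromosomes would fit, and so does weak binding gained by 16 h.

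The first 50 Mb of chromosome 5 held 173 peaks at 16 h and 17 at 1.5 h. A gain of binding at all strengths stays open, since the odds ratio of 16 h against 1.5 h was above 1 in each score class but rested on 9 against 3 peaks at scores of 100 or more (3.60, Fisher's exact test, p = 0.0756). This test replaced one between score classes within the 16 h list (2.39% in the segment at 100 or more, 6.20% under 60), which did not compare the times. A candidate explanation is more DNA or background of this segment in the 16 h library than in any control used for peak calling. An example is a copy number difference between cultures, which predicts an even spread. The low-score peaks occupied 42 of 50 bins of 1 Mb, within the range of 1000 even placements, whose lowest was 40 and median 46, but only 3.4% of placements gave 42 or fewer. The bins include a stretch with no peak of either list (46175019 to 49435691). With the 2 bins inside it left out, placements over the other 48 bins had a lowest of 37 and a median of 45. Of these placements, 10.7% gave 42 or fewer. That stretch was picked from these same lists, so an even spread is neither shown nor excluded. Of the 124 peaks scoring under 60 in the segment at 16 h, 0 overlapped a 1.5 h peak, against 95 of 1875 (5.07%) elsewhere (Fisher's exact test, p = 0.0036). The segment was drawn from these lists and held only 17 peaks at 1.5 h to overlap. Over all 16 h peaks, median width and score were 103 bp and 53.7 there, against 108 bp and 56.4 elsewhere (not tested). Newly gained binding and background could both lack such overlap. These values do not separate the 2, and the input library was not analysed here.

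Scores at 16 h were often tied. The value 52.99 was shared by 229 peaks at 16 h, and 69.4% of the 16 h peaks had a score that another peak also had, against 49.9% at 1.5 h. Of 304 bins of 10 Mb, 4 differed between the times in their share of peaks scoring under 60 (Fisher's exact test, Benjamini-Hochberg adjusted). The bins from 20 to 30 Mb and from 40 to 50 Mb of chromosome 5 were higher at 16 h, with 30 against 0 and 24 against 0 peaks. The other bins of its first 50 Mb did not pass but held 20 against 3, 28 against 1 and 22 against 1. The median over all bins was 6 at 16 h. The bins from 80 to 90 Mb of chromosome 16 and from 40 to 50 Mb of chromosome 20 were higher at 1.5 h, each with 8 against 1. Runs of 16 h peaks with no 1.5 h peak included one on chromosome 16 at 33963017 to 33975919 with 5 peaks and one on chromosome 10 at 42388989 to 42404714 with 4. Chromosome Y had 7 peaks at 16 h and none at 1.5 h. Of these 7, 2 scored 100 or more. They count among the 142 high-score peaks found only at 16 h, which were 140 on chromosomes 1 to 22 and X. Whether the peaks on chromosome Y mark binding was not tested.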
